A study of Mus musculus with 14 samples.

How the data were processed

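The study profiled natural killer T (NKT) cells, which are T cells that recognise lipids presented by the CD1d protein, sorted from the thymus of young male wild-type mice. Per the labels, mice received dexamethasone, a synthetic glucocorticoid, at 200 ug per 10 g body weight by injection into the peritoneum, or vehicle with 8% ethanol. Cells were taken 18 h or 3 d after dexamethasone, and the age-matched vehicle group was taken at 3 d, so the 18 h group has no vehicle group of its own time. There were 5 vehicle libraries, 5 libraries at 18 h and 4 libraries at 3 d. Per the labels' protocols, libraries were made from polyadenylated RNA by bulk MARS-seq, which sequences the 3′ end of transcripts, so a count reflects the transcript end and not the whole gene body. Per the submitters' processing notes the genome build was mm10, and the tools were bcl2fastq, cutadapt, STAR 2.5.2b, HTSeq and DESeq2, with no role or order given. How molecular identifiers and strand were handled is not given in the sources used here, so counts are not taken to be independent molecules and counting floors cover counting error only.

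The authors deposited 1 table for the whole series. Its raw columns are whole-number counts per gene, which the authors did not normalise. Each listed gene reached at least 6 counts in some library, so genes below that are not analysed here. The deposited normalized columns are a signal equal to the raw count divided by 1 size factor per library. The deposited log2 columns hold regularised log2 values per library and log2 fold changes of vehicle over 18 h, vehicle over 3 d and 18 h over 3 d. The deposited p-value columns hold p and adjusted p of those comparisons. Only the raw counts entered the tests here. The authors' fold changes and adjusted p were used for a comparison of calls, the regularised log2 values for the principal components, and the normalized columns were only checked against the raw counts.

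The table lists 10320 names, of which 17 were gene symbols turned into calendar dates, which cannot be assigned to single genes. These were left out and held 0.102% to 0.147% of the counts of a library. Total counts ranged from 977037 to 2203273 per library with a median of 1424351, and 9724 to 10137 listed genes had a count. The 10 most abundant genes took 8.64% to 11.9% of a library, and 1 count was worth 0.471 to 1.11 CPM, the count scaled to a fixed library total. Replicates of a group differed by more than counting noise in every pair (chi-square per degree of freedom 3.28 to 14.6), so none was merged with another, which does not show that they are separate samples. The labels do not say whether replicates are separate mice or pools, and p-values measure the spread between these samples.

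Counts were analysed in R 4.3.3 with edgeR 4.0.16. After the default expression filter by group, 7965 genes were tested. Libraries were scaled by TMM, and all 3 groups entered 1 robust quasi-likelihood fit, with no covariate. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called changed at an adjusted p below 0.05. Tests were two-sided. Fold changes are log2 with standard errors (SE) from the same fit, and levels are CPM after TMM scaling, as mean ± SD. The comparisons were 18 h against vehicle, 3 d against vehicle and 3 d against 18 h. The last is also the test of whether the effects against the shared 3 d vehicle group differ. It tests a change in the effect of dexamethasone only if vehicle cells at 18 h would equal those at 3 d.

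A set of 35 gene lists was fixed before the data were examined, covering the treatment, NKT subsets, cytokines, signalling, cell cycle, cell death, metabolism, RNA quality and the other cell types a thymic sort could hold. Lists were tested with camera in limma 3.58.1 on voom log2 CPM, with a preset correlation between genes of 0.01 and adjustment over the 30 lists with at least 3 tested members. Camera compares a list with all other genes. It was repeated with a correlation estimated from the data, and fry, which tests whether the members of a list move on balance in 1 direction without comparing them with other genes, was run beside it. With the estimated correlation, the calls that held were the glucocorticoid-induced, interferon-stimulated and DNA replication lists at 18 h, the DNA replication list at 3 d, and the NKT1, NKT2, interferon-stimulated and NK cell lists between the times.

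Genes to name were chosen by a rule fixed before the data were examined. It takes the 10 largest rises and 10 largest falls among called genes for each comparison with vehicle, and 5 and 5 between the times, with at least 20 CPM in the higher group and no overlap between groups, leaving out gene models and pseudogenes. It adds up to 4 called members of each list by smallest adjusted p. It always includes Il4, Il13, Areg, Il17rb, Gata3, Zbtb16, Tbx21, Ifng, Nr3c1, Tsc22d3, Fkbp5, Cd1d1, Rag1, Mki67 and Il4ra. The text names a selection of 82 genes from those that meet the rule, and that selection was made after their values were seen. Cd8b1, and the macrophage genes named without a call, were chosen after their values were seen. Some genes that meet the rule are not reported here. Areg and Rag1 were listed but fell below the expression filter and were not tested. Coordinates are from the RefSeq annotation of GRCm38, the assembly also called mm10.

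The procedure was tested on simulated counts drawn from the real means, dispersions and library sizes with 200 genes changed by known folds. For 18 h against vehicle, over 7770 genes, 66.7% of 2-fold and 95.9% of 4-fold changes were recovered, with 4 false calls among 164. For 3 d against vehicle, over 7760 genes, these values were 64.0% and 95.8%, with 9 false calls among 165. For 3 d against 18 h, over 7765 genes, they were 58.8% and 94.9%, with 9 false calls among 159. The number of lists called in the simulated data was 1, 0 and 0 of 30. Genes were drawn independently of each other there, so this does not test the list calls where members of a list are correlated.

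Alternatives chosen before the data were examined were other scalings (median-ratio size factors, upper quartile, library size without the 50 most abundant genes), no filter or a mean of at least 20 CPM, DESeq2 1.42.0, limma voom with sample quality weights, the replicate number as a block, only the groups compared in the fit, a 2-fold minimum, an adjusted p below 0.01, and leaving out each library in turn. Further alternatives were chosen after seeing the data. These left out the 18 h replicates 2 and 3, or those and vehicle replicate 3, removed each library's trend on transcript length and on the GC content of the last 500 bases (96.5% of tested genes had a GC content), or added each library's position on the axis from the other vehicle libraries to vehicle replicate 3 as a covariate.

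Counts cannot separate near-identical genes or, with strand handling unknown, genes that overlap on opposite strands. Histone genes, the Ly6c, Klra, Mx and Ifit families, and Ccr10, which overlaps Cntnap1 on the other strand, are therefore uncertain as single genes.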

Results

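Sorted thymic NKT cells were profiled by 3′ end sequencing in 5 vehicle libraries, 5 libraries taken 18 h after dexamethasone and 4 libraries taken 3 d after it. The series concerns regeneration of the thymus after injury and the part that type 2 immunity plays in it, and dexamethasone, which depletes developing thymocytes, was the injury. Total counts of vehicle replicates 1 to 5 were 2078540, 977037, 1986973, 1919298 and 1411557. Those of the 18 h replicates 1 to 5 were 1083680, 1073583, 1287843, 2203273 and 1437145, and those of the 3 d replicates 1 to 4 were 1496472, 1070861, 1158796 and 1517751. Group means were 1674681 ± 468083 for vehicle, 1417105 ± 464852 at 18 h and 1310970 ± 229477 at 3 d (SD). At these depths 1 count was worth 0.471 to 1.11 CPM, so genes of a few CPM are the least certain.

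Principal component 1 of the deposited regularised log2 values held 38.3% of the variance and separated vehicle from dexamethasone libraries. Component 2 held 18.7% and separated the 18 h (2.9 to 17.8) from the 3 d dexamethasone libraries (-20.9 to -12.7). Vehicle libraries, though taken at 3 d, lay at -2.4 to 4.8 on it. Vehicle replicate 3 lay at -9.9 on component 1, between the other vehicle libraries (-26.3 to -23.3) and the dexamethasone libraries (4.1 to 23.3). Cd8b1, a subunit of the CD8 coreceptor of conventional T cells and of developing CD4+CD8+ thymocytes, stood at 1008 and 648 CPM in the 18 h replicates 2 and 3 and at 9.4 to 71.2 CPM in the remaining libraries. All of these libraries were kept. Values written as a ± b after a gene are the log2 fold change and its SE, and adjusted p-values are from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Values for lists are the median log2 fold change and the adjusted p of camera.

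**Figure D1:**
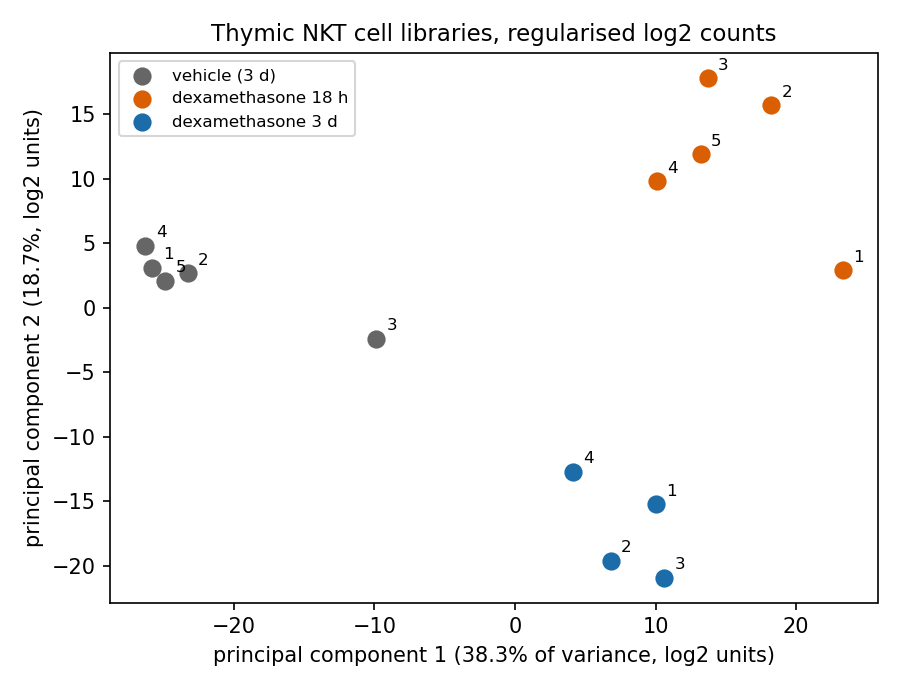
Each point is 1 of the 14 libraries, numbered by replicate, on principal components 1 (38.3% of variance) and 2 (18.7%) of the deposited regularised log2 values, coloured by group. Vehicle replicate 3 lies at -9.9 on component 1, apart from the other vehicle libraries at -26.3 to -23.3.

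The first comparison addressed the early response of thymic NKT cells to the glucocorticoid, 18 h after injection. Libraries of the sorted cells held more transcripts of glucocorticoid-induced and interferon-stimulated genes, and fewer transcripts of the type 1 (NKT1) programme and of DNA replication. Bulk counts cannot separate a change within cells from a change in the mix of cells sorted. Tsc22d3, which encodes the glucocorticoid-induced leucine zipper protein (chromosome X, 140539528 to 140600522), rose from 31 ± 8.53 to 387 ± 155 CPM (SD, n = 5 each; 3.63 ± 0.28, adjusted p = 5.2e-08 by edgeR). Xcl1, a chemokine made by NKT1 cells (chromosome 1, 164931644 to 164935522), fell from 541 ± 79.7 to 26.2 ± 9.94 CPM (-4.36 ± 0.22, adjusted p = 1.0e-11). In all, 2734 of 7965 genes (34.3%) changed, 1353 higher and 1381 lower. Of these, 1206 changed at least 2-fold, 734 higher and 472 lower. Libraries of the groups did not overlap for 1575 genes (19.8%, where chance gives 0.794%).

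Glucocorticoid-induced genes rose as a list (2.15, adjusted p = 1.1e-10), and 14 of the 16 tested members rose while the other 2 were not called (14 higher adjusted over the list alone). Fkbp5, a co-chaperone of the glucocorticoid receptor (chromosome 17, 28398753 to 28486149), rose from 50.4 ± 9.68 to 471 ± 96.1 CPM (3.21 ± 0.19, adjusted p = 7.0e-11). Pik3ip1, an inhibitor of phosphoinositide kinase signalling, rose by 3.07 ± 0.19 (adjusted p = 2.4e-10) and Ddit4, an inhibitor of mTOR signalling, by 2.45 ± 0.16 (adjusted p = 2.4e-10). The receptor gene itself, Nr3c1, rose from 80.0 ± 15.1 to 128 ± 41.6 CPM (0.67 ± 0.20, adjusted p = 0.011), a call that ended after each library's GC and length trend was removed (0.19 ± 0.17, adjusted p = 0.40).

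All 26 tested interferon-stimulated genes rose (26 adjusted over the list alone; 2.48, adjusted p = 2.4e-25). Usp18, a protease that limits interferon receptor signalling (chromosome 6, 121245906 to 121270917), rose from 35.1 ± 4.78 to 369 ± 70.8 CPM (3.39 ± 0.17, adjusted p = 1.0e-11). Isg15, a ubiquitin-like modifier, reached 2499 ± 401 CPM from 344 ± 59.9 CPM (2.86 ± 0.19, adjusted p = 6.4e-10). Oasl2, of the antiviral OAS family, rose by 2.43 ± 0.19 (adjusted p = 5.5e-09). Outside the list, the interferon-induced chemokine Cxcl10 rose by 4.28 ± 0.71 (adjusted p = 6.7e-04), and by more without vehicle replicate 3 (5.57 ± 0.67, adjusted p = 6.2e-05).

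Genes of the NKT1 subset, the NKT cells that make interferon gamma, fell as a list (-1.74, adjusted p = 5.6e-11, adjusted p = 0.21 with an estimated correlation). Of 21 tested members, 15 were lower and 6 not called (15 lower and 1 higher adjusted over the list alone). Ccl5, a chemokine of effector lymphocytes (chromosome 11, 83525778 to 83530518), fell from 1174 ± 174 to 183 ± 114 CPM (-2.69 ± 0.29, adjusted p = 2.6e-06). Klrb1c, which encodes the surface marker NK1.1, fell (-2.54 ± 0.28, adjusted p = 4.3e-06), as did the surface protein gene Ly6c2 (-2.46 ± 0.19, adjusted p = 7.5e-09). Tbx21, the type 1 regulator T-bet (chromosome 11, 97098007 to 97115331), fell from 190.4 ± 24.5 to 51.9 ± 39.6 CPM (-1.89 ± 0.39, adjusted p = 0.0022). Ifng, interferon gamma (chromosome 10, 118441046 to 118445894), fell from 134 ± 16.8 to 56.9 ± 44.3 CPM (-1.25 ± 0.34, adjusted p = 0.011). The list of type 1 cytokine and effector genes also fell (-0.67, adjusted p = 0.0088, adjusted p = 0.53 with an estimated correlation). Of 15 tested members, 6 were lower, 1 higher and 8 not called (6 lower and 2 higher adjusted over the list alone). In the 18 h replicate 1 the mean log2 CPM was 6.04 for type 1 cytokine genes (4.44 to 5.12 in the other 18 h libraries, 5.71 to 6.05 in vehicle) and 7.3 for NKT1 genes (5.45 to 6.08, and 7.65 to 8.1 in vehicle). Ifng stood at 132.1 CPM in that library, but Ccl5 at 378.8 CPM and Xcl1 at 40.1 CPM were below all vehicle libraries there too. Without the 18 h replicates 2 and 3, which carry Cd8b1, the NKT1 median was still called (-1.43, adjusted p = 2.0e-09) and that of type 1 cytokines was not (-0.56, adjusted p = 0.080). Outside these lists Gzmc, granzyme C, fell by 3.55 on the log2 scale (adjusted p = 5.5e-07). The NK cell and ILC1 list was not called (-0.72, adjusted p = 0.094), with 2 of 6 tested members lower (2 lower and 1 higher adjusted over the list alone). One of the lower members was Klrb1c, which is also in the NKT1 list. Camera called it with no filter on low counts (-0.87, adjusted p = 0.017) and without the 18 h replicate 1 (-1.1, adjusted p = 0.044).

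Type 2 genes did not move together at 18 h. Of 13 tested genes of the NKT2 subset, which makes interleukins 4 and 13, 2 rose, 3 fell and 8 were not called (2 higher and 3 lower adjusted over the list alone), and the list was not called (-0.37, adjusted p = 0.44). Il13 (chromosome 11, 53631323 to 53634702) fell from 85.4 ± 12.9 to 19.6 ± 9.49 CPM (-2.11 ± 0.25, adjusted p = 2.0e-06), and the zinc finger gene Hivep3 fell (-2.04 ± 0.26, adjusted p = 5.5e-06), while Plac8 rose (1.32 ± 0.26, adjusted p = 8.7e-04). Il4 (chromosome 11, 53612460 to 53618665) was 60.3 ± 23.3 CPM in vehicle and 44.8 ± 18.2 CPM at 18 h, which did not pass (-0.43 ± 0.27, adjusted p = 0.22). Zbtb16, which encodes the NKT regulator PLZF, did not pass (-0.46 ± 0.28, adjusted p = 0.22), although with sample quality weights it did (-0.75, adjusted p = 0.016). Gata3, the type 2 regulator (chromosome 2, 9857078 to 9887953), did not pass (0.31 ± 0.20, adjusted p = 0.26) but did without vehicle replicate 3 (0.50 ± 0.19, adjusted p = 0.044). Il17rb, a receptor subunit for the tuft cell cytokine interleukin 25, did not pass (0.85 ± 0.38, adjusted p = 0.10) but did without the 18 h replicate 2 (1.09 ± 0.26, adjusted p = 0.0038) and without replicates 2 and 3 (1.27 ± 0.24, adjusted p = 6.2e-04). Il4ra, the interleukin 4 receptor, rose (1.2 ± 0.39, adjusted p = 0.020). This call was lost without the 18 h replicate 3 (0.99 ± 0.40, adjusted p = 0.068) and without replicates 2 and 3 (0.75 ± 0.43, adjusted p = 0.20).

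Of 10 tested type 2 cytokine and signalling genes, 2 rose and 2 fell (2 and 2 adjusted over the list alone), and the list was not called (median 0.25, mean 0.01, adjusted p = 0.87). Of 10 tested genes of the interleukin 17-making NKT17 subset, 2 rose and 6 fell (2 and 6 adjusted over the list alone; -0.94, adjusted p = 0.083). That list was called without the 18 h replicate 5 (adjusted p = 0.045) and without the 3 d replicate 2 (adjusted p = 0.041), which is in the shared fit, and by fry (adjusted p = 0.0067). S100a4, a calcium-binding protein gene, fell by 2.55 on the log2 scale (adjusted p = 3.2e-05).

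DNA replication genes fell as a list (-1.07, adjusted p = 1.7e-10). Of 22 tested members, 20 were lower and 2 not called (20 lower adjusted over the list alone). Mcm5, a subunit of the replicative helicase, fell from 197 ± 40.5 to 70.7 ± 5.94 CPM (-1.48 ± 0.15, adjusted p = 3.8e-07). Rrm2, a subunit of ribonucleotide reductase, fell by 2.11 (adjusted p = 3.4e-05). Mitosis genes fell (-0.81, adjusted p = 5.1e-06, adjusted p = 0.53 with an estimated correlation). Their mean log2 CPM was 4.01, 3.87 and 4.83 in the 18 h replicates 1, 4 and 5. In replicates 2 and 3, which carry Cd8b1, it was 5.13 and 5.16, within the vehicle range (5.12 to 5.62). Of 27 tested members, 14 were lower and 13 not called (15 lower adjusted over the list alone). Called ones included Cenpa, the centromeric histone (-1.10 ± 0.20, adjusted p = 2.3e-04), and Ccna2, cyclin A2 (-1.78 ± 0.38, adjusted p = 0.0013), which was lower still without the 18 h replicate 3 (-2.38 ± 0.34, adjusted p = 3.8e-05) or replicates 2 and 3 (-2.75 ± 0.36, adjusted p = 1.1e-05). Mki67, the proliferation marker Ki-67 (chromosome 7, 135689784 to 135716450), was 33.2 ± 13.7 CPM in vehicle and 40.6 ± 19.4 CPM at 18 h (0.23 ± 0.34, adjusted p = 0.63). Oxidative phosphorylation genes fell (-0.47, adjusted p = 1.9e-06, adjusted p = 0.53 with an estimated correlation). Of 34 tested members, 21 were lower and 13 not called (22 lower adjusted over the list alone). Called ones included the ATP synthase subunit gene Atp5g1 (-1.09 ± 0.18, adjusted p = 9.9e-05). Ribosome biogenesis genes fell (-0.43, adjusted p = 0.0018, adjusted p = 0.59 with an estimated correlation). Of 29 tested members, 10 were lower and 19 not called (10 lower adjusted over the list alone).

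Targets of the inflammatory factor NF-kB rose (0.53, adjusted p = 0.0010, adjusted p = 0.43 with an estimated correlation). Of 18 tested members, 8 were higher, 1 lower and 9 not called (9 and 1 adjusted over the list alone). Nfkbia, which encodes an inhibitor of NF-kB, rose by 1.84 ± 0.20 (adjusted p = 1.1e-06) and Birc3, an inhibitor of apoptosis, by 1.78 ± 0.27 (adjusted p = 5.3e-05). Nfkbia is also a member of the glucocorticoid-induced list, so its rise is not particular to NF-kB targets. Apoptosis genes went both ways, with 6 of 18 higher and 4 lower (6 and 4 adjusted over the list alone; 0.05, adjusted p = 0.69). The BH3-only genes Bbc3, which encodes PUMA, and Bmf rose by 1.61 ± 0.20 (adjusted p = 4.7e-06) and 3.11 ± 0.43 (adjusted p = 2.4e-05), the latter by less without the 18 h replicates 2 and 3 (2.45 ± 0.39, adjusted p = 1.1e-04). The death receptor gene Fas rose by 1.95 ± 0.33 (adjusted p = 1.3e-04). Of 17 pro-survival genes, 7 rose and 4 fell (7 and 4 adjusted over the list alone; 0.52, adjusted p = 0.33). Of 17 trafficking genes, 7 rose and 6 fell (8 and 6 adjusted over the list alone; 0.01, adjusted p = 0.86). The chemokine receptor gene Cxcr4 rose from 23.5 ± 4.52 to 140.2 ± 53.4 CPM (2.57 ± 0.24, adjusted p = 1.4e-07). S1pr1 and Klf2, which act in thymic egress, rose by 1.66 ± 0.26 (adjusted p = 5.7e-05) and 1.90 ± 0.40 (adjusted p = 0.0026). Without the 18 h replicates 2 and 3 the Klf2 rise was smaller (1.14 ± 0.30, adjusted p = 0.010).

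Markers of conventional single-positive T cells rose as a list (1.58, adjusted p = 0.022, adjusted p = 0.66 with an estimated correlation). Of 14 tested members, 6 were higher, 1 lower and 7 not called (6 and 1 adjusted over the list alone). Called ones included the endosomal protein gene Nsg2 (1.5 ± 0.28, adjusted p = 7.2e-04). This call was lost without vehicle replicate 3 (adjusted p = 0.064), without the 18 h replicate 2 (adjusted p = 0.13), without the 18 h replicate 3 (adjusted p = 0.088) and without both of those 18 h libraries, which carry Cd8b1 (0.23, adjusted p = 0.71). It was also lost with the GC and length trend removed, where the median was close to that of the main fit (1.46, adjusted p = 0.075), and in fry (adjusted p = 0.098). Among 14 tested genes of CD4+CD8+ thymocytes, which also carry Cd8b1, 5 rose and 4 fell (7 and 4 adjusted over the list alone). That list was not called (median 0.52, mean 0.23, adjusted p = 0.96). Its mean log2 CPM was 5.4 and 5.26 in the 18 h replicates 2 and 3. The other 18 h libraries had 3.95 to 4.41 and vehicle 4.55 to 5.11. Of 8 regulatory T cell genes, 4 rose and 1 fell (4 and 1 adjusted over the list alone; 0.37, adjusted p = 0.56), with the inhibitory receptor gene Ctla4 higher by 4.91 ± 0.42 (adjusted p = 3.7e-08). Of 17 macrophage genes, 5 rose and 1 fell (5 and 1 adjusted over the list alone; 0.47, adjusted p = 0.43). Higher ones included the mannose receptor gene Mrc1 (3.75 ± 0.72, adjusted p = 4.2e-04) and Ctss, the lysosomal protease cathepsin S (1.16 ± 0.16, adjusted p = 1.7e-05). That list was called without the 18 h replicate 4 (0.78, adjusted p = 0.0078). Cd1d1, which encodes the lipid-presenting molecule NKT cells are selected on, rose by 0.73 ± 0.22 (adjusted p = 0.013). It was not called without the 18 h replicates 2 and 3 (0.62 ± 0.25, adjusted p = 0.075). Immediate early and heat shock genes, a mark of handling, rose (0.62, adjusted p = 0.023, adjusted p = 0.53 with an estimated correlation). Of 21 tested members, 6 were higher (8 adjusted over the list alone). That call ended without the 18 h replicate 1 (adjusted p = 0.057) or 4 (adjusted p = 0.070) and with a mean of at least 20 CPM required of each gene (adjusted p = 0.056) or sample quality weights (adjusted p = 0.054). Ribosomal protein genes fell (-0.24, adjusted p = 0.029, adjusted p = 0.66 with an estimated correlation). Of 38 tested members, 10 were lower and 2 higher (10 and 1 adjusted over the list alone). The call ended without vehicle replicate 3 (adjusted p = 0.13), the 18 h replicate 1 (adjusted p = 0.096) or 3 (adjusted p = 0.089) or the 18 h replicates 2 and 3 (adjusted p = 0.11), with only the groups compared in the fit (adjusted p = 0.060), with at least 20 CPM required (adjusted p = 0.069), in fry (adjusted p = 0.051), and with the GC and length trend removed (-0.02, adjusted p = 0.84).

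Among the largest changes, Plaur, the urokinase receptor gene, rose by 4.96 ± 0.51 (adjusted p = 8.2e-06; 5.66 ± 0.54, adjusted p = 5.8e-06 without vehicle replicate 3), Trnp1, a nuclear protein gene, by 6.50 ± 0.67 (adjusted p = 8.5e-06) and the surface protein gene Ly6c1 by 4.41 ± 0.34 (adjusted p = 6.5e-09). The zinc transporter gene Tmem163 fell from 20.7 ± 3.88 to 0.265 ± 0.388 CPM (adjusted p = 1.7e-08) and the growth factor gene Pdgfb was lower (-2.74 ± 0.34, adjusted p = 6.3e-06). Saa3, an acute-phase serum amyloid gene, and Neb, a muscle structural gene, had 0 counts over the vehicle group and 180 and 164 counts at 18 h, at least 65.3-fold and at least 59.5-fold higher when 3 counts over the group are taken as the floor. With the axis of vehicle replicate 3 as a covariate, which in effect sets dexamethasone against that single vehicle library, 539 genes were called. Under it Ifng, Plac8, Il4ra, Ccna2, Cenpa, Fas, Birc3, Klf2, Nr3c1 and Cd1d1 were not called (adjusted p = 0.06 to 0.51). The fold was larger than without the covariate for Ifng (-1.66 ± 0.49), Plac8 (1.45 ± 0.43) and Il4ra (1.75 ± 0.65), with larger SE. It was smaller for all the others of these genes. Without the 18 h replicates 2 and 3, 2185 genes changed, and without these and vehicle replicate 3, 2735.

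**Figure D2:**
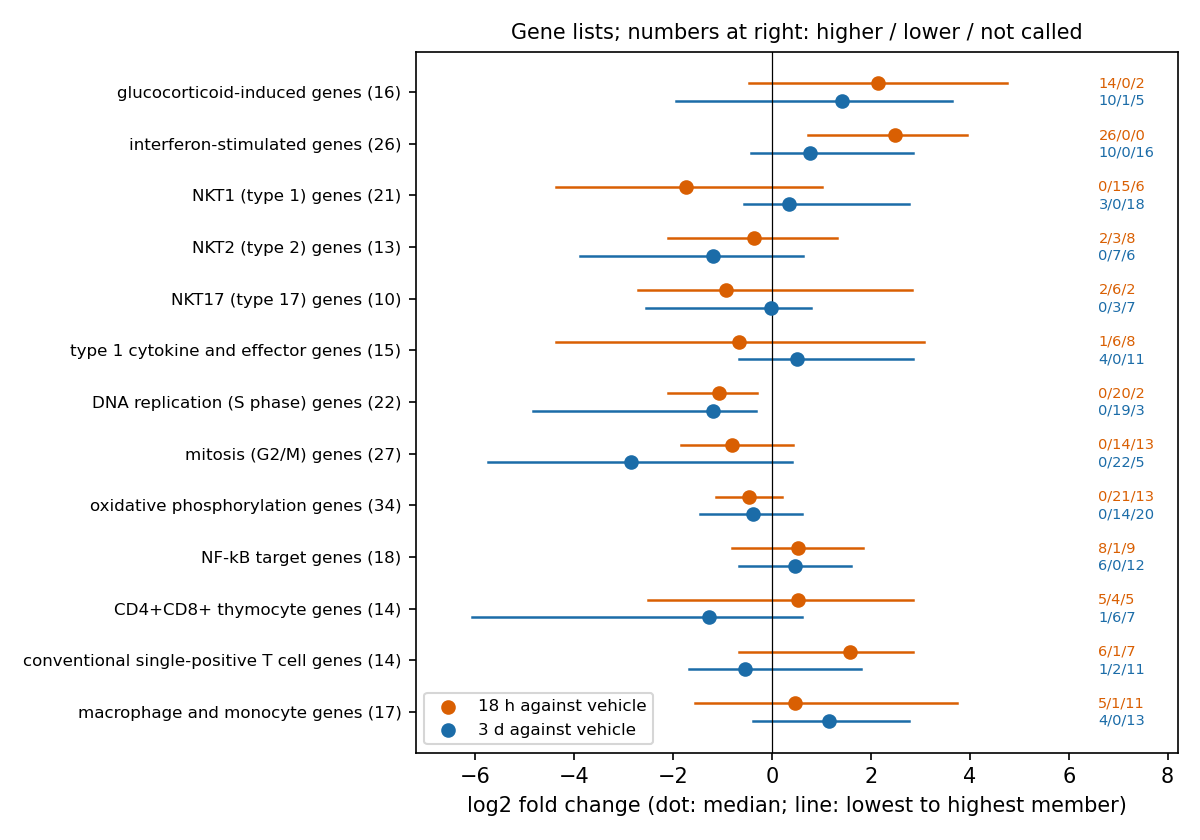
Median log2 fold change (dots) and range from the lowest to the highest tested member (lines) of 13 gene lists at 18 h and 3 d against vehicle, with the number of members higher, lower and not called. The interferon-stimulated median was 2.48 at 18 h and 0.76 at 3 d, and the NKT1 median was -1.74 and 0.34.

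The second comparison addressed the later response, 3 d after dexamethasone, against vehicle of the same time. At 3 d the libraries of sorted cells held fewer transcripts of cell division and of several type 2 genes, while glucocorticoid-induced genes were still higher. The same limit of bulk counts applies here. Il13 fell from 85.4 ± 12.9 CPM (SD, n = 5) to 5.54 ± 2.37 CPM (n = 4; -3.88 ± 0.32, adjusted p = 5.5e-08 by edgeR). Birc5, the mitotic regulator survivin (chromosome 11, 117849237 to 117855743), fell from 72.7 ± 9.87 to 4.40 ± 2.75 CPM (-3.97 ± 0.39, adjusted p = 6.9e-07). In all, 2064 of 7965 genes (25.9%) changed, 964 higher and 1100 lower, of which 916 changed at least 2-fold, 446 higher and 470 lower. Libraries of the groups did not overlap for 1717 genes (21.6%, where chance gives 1.59%).

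Genes of the NKT2 subset fell as a list (-1.2, adjusted p = 2.1e-04, adjusted p = 0.075 with an estimated correlation). Of 13 tested members, 7 were lower and 6 not called (7 lower adjusted over the list alone). Zbtb16, which encodes PLZF (chromosome 9, 48651797 to 48836225), fell from 69.1 ± 16.7 to 18.2 ± 5.83 CPM (-1.94 ± 0.34, adjusted p = 5.1e-04), and Hivep3 fell by 3.27 (adjusted p = 5.0e-07). Stmn1, a microtubule regulator also tied to division, fell by 3.02 (adjusted p = 4.0e-06). Il4 was 60.3 ± 23.3 CPM in vehicle and 54.6 ± 6.17 CPM at 3 d (-0.17 ± 0.28, adjusted p = 0.69), and Il4ra did not pass (0.62 ± 0.43, adjusted p = 0.29). Gata3 did not pass (0.35 ± 0.22, adjusted p = 0.24) but did without vehicle replicate 3 (0.54 ± 0.20, adjusted p = 0.043) and with sample quality weights (0.50, adjusted p = 0.022). Il17rb was 123 ± 17.7 CPM in vehicle and 72.3 ± 20.9 CPM at 3 d (-0.76 ± 0.43, adjusted p = 0.21). It passed without the 18 h replicate 2 (-0.75 ± 0.27, adjusted p = 0.048) or replicates 2 and 3 (-0.75 ± 0.24, adjusted p = 0.024) in the shared fit, and with only the groups compared in the fit (-0.75 ± 0.19, adjusted p = 0.0050). Of 10 type 2 cytokine and signalling genes, 1 rose and 2 fell (2 and 2 adjusted over the list alone; median 0.15, mean -0.26, adjusted p = 0.87). The NKT precursor list fell (-0.78, adjusted p = 0.029, adjusted p = 0.53 with an estimated correlation). Of 12 tested members, 5 were lower, 1 higher and 6 not called (5 and 1 adjusted over the list alone). Called ones included Tox, a regulator of thymocyte development (-2.17 ± 0.37, adjusted p = 6.0e-04). The list's call ended with a mean of at least 20 CPM required (-0.52, adjusted p = 0.26) and without vehicle replicate 3 (adjusted p = 0.063) or the 3 d replicate 2 (adjusted p = 0.051), and with sample quality weights (adjusted p = 0.072).

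Mitosis genes fell (-2.85, adjusted p = 1.8e-16, adjusted p = 0.19 with an estimated correlation). Of 27 tested members, 22 were lower and 5 not called (23 lower adjusted over the list alone). Aurkb, the mitotic kinase Aurora B, fell by 3.40 (adjusted p = 9.3e-07), and Cenpa was lower (-2.46 ± 0.23, adjusted p = 2.9e-07). Mki67 fell from 33.2 ± 13.7 to 5.02 ± 2.42 CPM (-2.74 ± 0.48, adjusted p = 5.2e-04). DNA replication genes fell (-1.2, adjusted p = 8.0e-14). Of 22 tested members, 19 were lower and 3 not called (21 lower adjusted over the list alone). Called ones included Mcm5 (-1.56 ± 0.17, adjusted p = 1.3e-06) and Rrm2 (-3.48 ± 0.39, adjusted p = 2.9e-06; -4.32 ± 0.43, adjusted p = 1.5e-06 without the 3 d replicate 4). The histone genes Hist1h3c and Hist1h2ab, near-identical to others of their cluster, were lower (-5.30 ± 0.40, adjusted p = 2.5e-08 and -5.45 ± 0.44, adjusted p = 5.5e-08). Oxidative phosphorylation genes fell (-0.38, adjusted p = 1.1e-04, adjusted p = 0.53 with an estimated correlation). Of 34 tested members, 14 were lower and 20 not called (16 lower and 1 higher adjusted over the list alone). Called ones included Atp5g3 (-1.46 ± 0.21, adjusted p = 4.8e-05).

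Type 1 genes were higher at 3 d, close to the threshold. The NKT1 list rose (0.34, adjusted p = 0.037, adjusted p = 0.64 with an estimated correlation). Of 21 tested members, 3 were higher and 18 not called (3 higher adjusted over the list alone). The list of type 1 cytokines rose (0.50, adjusted p = 0.033, adjusted p = 0.53 with an estimated correlation). Of 15 tested members, 4 were higher and 11 not called (4 higher adjusted over the list alone). Gzma, granzyme A, rose from 59.7 ± 20 to 413 ± 91.6 CPM (2.77 ± 0.40, adjusted p = 2.9e-04), Ccl5 from 1174 ± 174 to 4251 ± 378 CPM (1.86 ± 0.28, adjusted p = 1.8e-04), and the chemokine gene Ccl4 by 1.31 ± 0.35 (adjusted p = 0.0098). The lectin-like receptor gene Klre1 rose (1.82 ± 0.54, adjusted p = 0.022). Its call was lost without vehicle replicate 1 (adjusted p = 0.057), 4 (adjusted p = 0.051) or 5 (adjusted p = 0.051) or the 3 d replicate 3 (adjusted p = 0.098). Tbx21 did not pass (0.35 ± 0.38, adjusted p = 0.53). Neither did Ifng, at 235 ± 15.6 CPM (0.80 ± 0.34, adjusted p = 0.091), which passed without the 18 h replicate 1 (0.81 ± 0.19, adjusted p = 0.0030), replicate 2 (0.81 ± 0.28, adjusted p = 0.044) or replicates 2 and 3 (0.81 ± 0.21, adjusted p = 0.0085) in the shared fit, with only the groups compared in the fit (0.81 ± 0.14, adjusted p = 2.1e-04) and with sample quality weights (0.88, adjusted p = 0.0019). The NKT1 call ended without vehicle replicate 1 (adjusted p = 0.067) or 3 (adjusted p = 0.051) and without the 3 d replicate 3 (adjusted p = 0.14) or 4 (adjusted p = 0.074). The type 1 cytokine call ended without vehicle replicate 3 (adjusted p = 0.051) or the 3 d replicates 3 (adjusted p = 0.063) or 4 (adjusted p = 0.052). With at least 20 CPM required both calls ended (adjusted p = 0.064 for NKT1 and adjusted p = 0.088 for type 1 cytokines), and fry called neither (adjusted p = 0.19 and adjusted p = 0.078).

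Glucocorticoid-induced genes stayed above vehicle (1.41, adjusted p = 2.5e-07, adjusted p = 0.075 with an estimated correlation). Of 16 tested members, 10 were higher, 1 lower and 5 not called (10 and 1 adjusted over the list alone). The lower member was Zbtb16. Tsc22d3 stood at 389 ± 41.2 CPM (3.64 ± 0.29, adjusted p = 2.1e-07), Fkbp5 at 180.0 ± 39.9 CPM (1.82 ± 0.19, adjusted p = 9.3e-07) and Pik3ip1 at 145 ± 15.9 CPM (2.32 ± 0.20, adjusted p = 7.8e-08). Nr3c1 (0.40 ± 0.21, adjusted p = 0.16) and Cd1d1 (0.48 ± 0.23, adjusted p = 0.13) did not pass, although with sample quality weights both did (0.53, adjusted p = 0.017 and 0.66, adjusted p = 0.016). Interferon-stimulated genes rose (0.76, adjusted p = 8.6e-04, adjusted p = 0.53 with an estimated correlation). Of 26 tested members, 10 were higher and 16 not called (14 higher adjusted over the list alone). Fry did not call this list (adjusted p = 0.057). Called ones included Irf7, an interferon regulatory factor (1.28 ± 0.19, adjusted p = 6.4e-05), and Usp18 (0.81 ± 0.18, adjusted p = 0.0029).

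NF-kB targets rose (0.46, adjusted p = 4.4e-04, adjusted p = 0.35 with an estimated correlation). Of 18 tested members, 6 were higher and 12 not called (6 higher adjusted over the list alone). Called ones included Tnfaip3, the inhibitor A20 (1.35 ± 0.19, adjusted p = 3.6e-05), and Nfkbia (1.32 ± 0.21, adjusted p = 1.3e-04), which is also in the glucocorticoid-induced list. Pro-survival genes rose (0.43, adjusted p = 0.027, adjusted p = 0.42 with an estimated correlation). Of 17 tested members, 6 were higher and 1 lower (7 and 2 adjusted over the list alone). This call ended without vehicle replicate 3 (adjusted p = 0.051) or the 3 d replicate 4 (adjusted p = 0.060), and with at least 20 CPM required (adjusted p = 0.073). Bcl2 rose from 80.8 ± 11.7 to 239 ± 59.2 CPM (1.56 ± 0.33, adjusted p = 0.0031), Cflar, an inhibitor of death receptor signalling, by 0.94 ± 0.21 (adjusted p = 0.0021) and Birc3 by 1.42 ± 0.29 (adjusted p = 0.0014). Of 17 T cell receptor activation genes 3 rose and 5 fell (3 and 6 adjusted over the list alone; median 0.15, mean -0.13, adjusted p = 0.71), with the costimulator gene Icos lower (-1.35 ± 0.23, adjusted p = 2.7e-04) and the activation-induced factor Irf4 lower (-1.75 ± 0.35, adjusted p = 0.0010). Immediate early and heat shock genes rose (0.59, adjusted p = 0.0014, adjusted p = 0.42 with an estimated correlation). Of 21 tested members, 5 were higher (5 adjusted over the list alone). Of 17 trafficking genes 5 rose and 1 fell (5 and 1 adjusted over the list alone; 0.24, adjusted p = 0.084). The list was called without the 3 d replicate 2 (adjusted p = 0.042) and by fry (adjusted p = 0.012). Cxcr4 rose by 3.13 ± 0.25 (adjusted p = 5.5e-08).

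Macrophage genes were higher at 3 d (1.16, adjusted p = 4.1e-04, adjusted p = 0.53 with an estimated correlation). Of 17 tested members, 4 were higher and 13 not called (10 higher adjusted over the list alone), and fry did not call the list (adjusted p = 0.078). Apoe, the lipid carrier apolipoprotein E (chromosome 7, 19696244 to 19701310), rose from 457 ± 134 to 3126 ± 1839 CPM (2.78 ± 0.46, adjusted p = 7.4e-04). Its neighbour Apoc1 (chromosome 7, 19689480 to 19692659) rose by 3.86 ± 0.61 (adjusted p = 6.1e-04), and by less without the 3 d replicate 1 (3.13 ± 0.52, adjusted p = 0.0011). Ctss rose by 0.84 ± 0.17 (adjusted p = 0.0013). The complement gene C1qa rose (1.52 ± 0.43, adjusted p = 0.019) but not without the 3 d replicate 1 (1.09 ± 0.41, adjusted p = 0.075), nor without the 18 h replicates 2 and 3 and vehicle replicate 3 (1.43 ± 0.53, adjusted p = 0.067). Spi1, the myeloid regulator PU.1, rose (1.82 ± 0.54, adjusted p = 0.019) but not without vehicle replicate 1 (adjusted p = 0.054) or 4 (adjusted p = 0.053) or the 3 d replicate 1 (adjusted p = 0.12).

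Markers of CD4+CD8+ thymocytes, the cells that dexamethasone depletes, fell (-1.28, adjusted p = 0.037, adjusted p = 0.52 with an estimated correlation). Of 14 tested members, 6 were lower, 1 higher and 7 not called (6 and 1 adjusted over the list alone). Dntt, which encodes terminal deoxynucleotidyl transferase, fell from 25.3 ± 11.4 to 0.550 ± 0.376 CPM (adjusted p = 4.0e-04), and the nuclease gene Endou from 18.6 ± 8.04 to 0.172 ± 0.344 CPM (adjusted p = 3.0e-05), with its only 3 d count in replicate 4. The aquaporin gene Aqp11 was lower (-2.20 ± 0.35, adjusted p = 1.2e-04). With a mean of at least 20 CPM required of each gene the median was 0 and the list was not called (adjusted p = 0.91). That mean covers all libraries, so members that fell, such as Aqp11 (26.6 CPM in vehicle and 5.49 CPM at 3 d), were more readily left out. The result therefore does not show which members carried the fall. The list's call also ended without vehicle replicate 3 (adjusted p = 0.061) or the 3 d replicates 2 (adjusted p = 0.051), 3 (adjusted p = 0.085) or 4 (adjusted p = 0.060), and with sample quality weights (adjusted p = 0.072). The gamma-delta T cell list of 4 tested genes fell (-2.65, adjusted p = 0.045, adjusted p = 0.44 with an estimated correlation), with 2 lower (3 lower and 1 higher adjusted over the list alone), namely the scavenger receptor gene Cd163l1 (-2.74 ± 0.37, adjusted p = 2.7e-05) and the kinase gene Blk (-2.55 ± 0.69, adjusted p = 0.014). Without the 3 d replicate 2 Blk was lower still (-3.65 ± 0.72, adjusted p = 0.0031), as was the list (-3.25, adjusted p = 0.037). The list's call ended without vehicle replicate 3 (adjusted p = 0.072), the 18 h replicate 1 (adjusted p = 0.051) or the 3 d replicates 1 (adjusted p = 0.098), 3 (adjusted p = 0.067) or 4 (adjusted p = 0.094).

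Ccr10, a chemokine receptor gene that overlaps Cntnap1 and is uncertain, fell by 5.01 (adjusted p = 3.1e-05), while Ly6c1 and Trnp1 were higher by 3.24 ± 0.37 (adjusted p = 3.3e-06) and 3.39 ± 0.81 (adjusted p = 0.0081). Saa3 and Neb, with 0 counts in vehicle, were at least 11.2-fold and at least 5.1-fold higher at 3 d. With the axis of vehicle replicate 3 as a covariate 228 genes were called, 21.9% of them higher against 46.7% without the covariate. Under it Zbtb16, Gzma, Ccl5, Klre1, Ccl4, Usp18, Apoe, Apoc1, C1qa, Ctss, Spi1, Tox, Irf4, Bcl2, Cflar, Birc3, Nfkbia, Trnp1, Blk and Atp5g3 were not called (adjusted p = 0.058 to 0.80). The fold was larger than without the covariate for Apoe (3 ± 0.89), Apoc1 (4.85 ± 1.21), C1qa (1.82 ± 0.78) and Trnp1 (3.48 ± 1.25), with larger SE. It was smaller for all the others of these genes. Without vehicle replicate 3 and the 18 h replicates 2 and 3, 2721 genes changed.

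**Figure D3:**
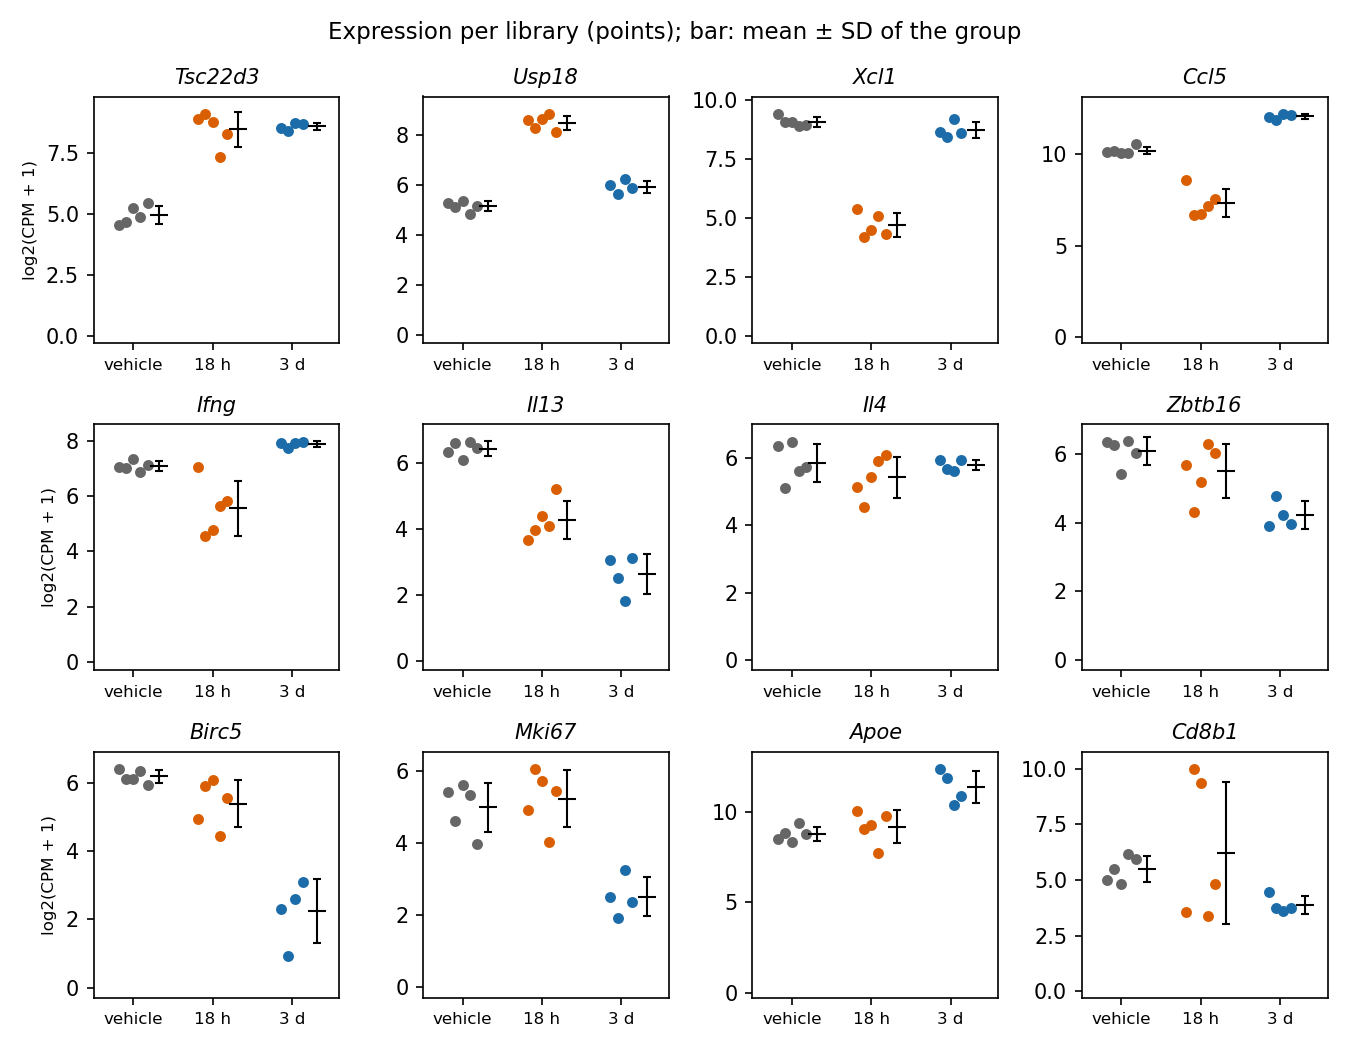
Expression of 12 genes as log2(CPM + 1) in each library (points) with group mean ± SD, for 5 libraries of vehicle, 5 of 18 h and 4 of 3 d. Usp18 averaged 369 CPM at 18 h and 61.5 CPM at 3 d, Il13 fell from 85.4 CPM in vehicle to 5.54 CPM at 3 d, and Cd8b1 reached 1008 CPM in a single 18 h library.

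The third comparison set 3 d directly against 18 h and so tested which effects against the shared vehicle group differ. Without vehicle at 18 h, a change with time after injection alone cannot be told apart from it. From 18 h to 3 d, NKT1 genes were higher, and interferon-stimulated, NKT2 and mitosis genes were lower. In all, 931 of 7965 genes (11.7%) changed, 381 higher and 550 lower, of which 588 changed at least 2-fold, 193 higher and 395 lower. Libraries did not overlap for 888 genes (11.1%, where chance gives 1.59%). The number higher was 242 without the 18 h replicate 3 and 252 without the 3 d replicate 2. Without the 18 h replicates 2 and 3, 660 genes changed, 233 higher and 427 lower, and without these and vehicle replicate 3, 727.

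NKT1 genes rose (2.06, adjusted p = 6.7e-29). Of 21 tested members, 17 were higher and 4 not called (20 higher adjusted over the list alone). Ccl5 went from 183 ± 114 CPM at 18 h (SD, n = 5) to 4251 ± 378 CPM at 3 d (n = 4; 4.54 ± 0.31, adjusted p = 6.7e-08 by edgeR), and Xcl1 from 26.2 ± 9.94 to 430.2 ± 107 CPM (4.03 ± 0.23, adjusted p = 1.4e-10). Ifng went from 56.9 ± 44.3 to 235 ± 15.6 CPM (2.06 ± 0.35, adjusted p = 0.0013). Tbx21 rose by 2.23 ± 0.40 (adjusted p = 0.0024), Klrb1c by 2.84 ± 0.29 (adjusted p = 7.3e-06) and Ly6c2 by 2.86 ± 0.20 (adjusted p = 4.0e-09). Type 1 cytokines rose (1.15, adjusted p = 1.1e-09, adjusted p = 0.080 with an estimated correlation), and by more without the 18 h replicate 1 (1.75, adjusted p = 4.1e-13). Of 15 tested members, 7 were higher and 8 not called (10 higher adjusted over the list alone). The NK cell and innate lymphoid list rose (1.17, adjusted p = 2.9e-05). Of 6 tested members, 2 were higher (4 adjusted over the list alone), Klrb1c and Gzma. Both are also in the NKT1 list, so this rise is not separate from that of NKT1 genes. Interferon-stimulated genes fell (-1.55, adjusted p = 2.2e-32). Of 26 tested members, 24 were lower and 2 not called (25 lower adjusted over the list alone). Called ones included Usp18 (-2.58 ± 0.18, adjusted p = 4.0e-09), Isg15 (-2.43 ± 0.21, adjusted p = 6.7e-08) and Oasl2 (-2.45 ± 0.21, adjusted p = 6.7e-08).

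NKT2 genes fell from 18 h to 3 d (-1.23, adjusted p = 1.1e-05). Of 13 tested members, 8 were lower and 5 not called (9 lower adjusted over the list alone). Il13 fell (-1.77 ± 0.35, adjusted p = 0.0017), as did Zbtb16 (-1.49 ± 0.34, adjusted p = 0.0071), the interleukin 6 receptor gene Il6ra (-1.61 ± 0.25, adjusted p = 1.7e-04), Stmn1 (-2.17 ± 0.32, adjusted p = 2.0e-04) and Id3, an inhibitor of E proteins (-2.02 ± 0.39, adjusted p = 0.0034). Il17rb fell (-1.60 ± 0.43, adjusted p = 0.026), a call lost without the 3 d replicates 2 (adjusted p = 0.064), 3 (adjusted p = 0.083) or 4 (adjusted p = 0.053), with only the groups compared in the fit (adjusted p = 0.068) and with sample quality weights (adjusted p = 0.073). Il4 (0.27 ± 0.29, adjusted p = 0.62), Gata3 (0.04 ± 0.22, adjusted p = 0.93) and Il4ra (-0.57 ± 0.40, adjusted p = 0.40) did not pass. The NKT precursor list fell (-0.86, adjusted p = 0.0027, adjusted p = 0.27 with an estimated correlation). Of 12 tested members, 4 were lower and 8 not called (5 lower adjusted over the list alone). That call ended without the 18 h replicates 2 and 3 (adjusted p = 0.055) and in fry (adjusted p = 0.055). Without the same 18 h libraries Stmn1 fell less (-1.55 ± 0.22, adjusted p = 9.0e-05). Mitosis genes fell (-2.17, adjusted p = 1.2e-13, adjusted p = 0.17 with an estimated correlation), also by less without them (-1.55, adjusted p = 1.0e-11). Of 27 tested members, 21 were lower and 6 not called (23 lower adjusted over the list alone). Examples were Birc5 (-3.25 ± 0.40, adjusted p = 1.7e-05), Aurkb (-2.29 ± 0.37, adjusted p = 2.6e-04) and Mki67 (-2.97 ± 0.48, adjusted p = 3.9e-04). DNA replication genes were not called (-0.25, adjusted p = 0.057). Of 22 tested members, 4 were lower and 1 higher (6 and 1 adjusted over the list alone). They were called without vehicle replicate 4 (adjusted p = 0.048) or 5 (adjusted p = 0.045) and without the 18 h replicate 1 (adjusted p = 0.034) or 3 (adjusted p = 0.040).

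Glucocorticoid-induced genes fell back (-0.75, adjusted p = 2.8e-04, adjusted p = 0.16 with an estimated correlation). Of 16 tested members, 8 were lower and 8 not called (9 lower adjusted over the list alone). Fkbp5 (-1.39 ± 0.18, adjusted p = 2.6e-05) and Ddit4 (-1.34 ± 0.16, adjusted p = 8.4e-06) were lower at 3 d. Tsc22d3 did not differ detectably (0.01 ± 0.26, adjusted p = 0.98), nor did Nr3c1 (-0.27 ± 0.21, adjusted p = 0.46) or Cd1d1 (-0.25 ± 0.23, adjusted p = 0.54). Conventional T cell genes were lower at 3 d (-1.53, adjusted p = 2.2e-04, adjusted p = 0.34 with an estimated correlation). Of 14 tested members, 7 were lower and 7 not called (10 lower adjusted over the list alone). Called ones included Nsg2 (-2.78 ± 0.33, adjusted p = 3.7e-05) and the lymph node homing receptor gene Ccr7 (-2.70 ± 0.56, adjusted p = 0.0065). The 18 h replicates 2 and 3, with Cd8b1 at 1008 and 648 CPM, carried most of this difference. Without them the fall was smaller for the list (-0.37, adjusted p = 0.040) and for Ccr7 (-1.54 ± 0.29, adjusted p = 0.0018), and fry did not call the list (adjusted p = 0.069). Markers of CD4+CD8+ thymocytes fell (-1.23, adjusted p = 0.0027, adjusted p = 0.24 with an estimated correlation). Of 14 tested members, 4 were lower (11 adjusted over the list alone). Without the 18 h replicates 2 and 3 the fall was smaller (-0.63, adjusted p = 0.045), and with at least 20 CPM required the list was not called (-0.79, adjusted p = 0.15). ILC2 genes, markers of type 2 innate lymphoid cells, fell too (-1.29, adjusted p = 0.0097, adjusted p = 0.27 with an estimated correlation). Of 6 tested members, 3 were lower (5 lower and 1 higher adjusted over the list alone).

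Macrophage genes rose (0.76, adjusted p = 0.0028, adjusted p = 0.49 with an estimated correlation). Of 17 tested members, 2 were higher and 1 lower (5 and 1 adjusted over the list alone). This call ended without the 18 h replicate 4 (adjusted p = 0.16) or the 3 d replicate 1 (adjusted p = 0.074) and in fry (adjusted p = 0.22). Apoe rose (2.22 ± 0.45, adjusted p = 0.0052), though not without the 18 h replicates 2 and 3 (2.09 ± 0.59, adjusted p = 0.055), and Apoc1 rose by 3.72 ± 0.60 (adjusted p = 0.0012; 3.02 ± 0.51, adjusted p = 0.0020 without the 3 d replicate 1). Among the largest changes, the interferon-inducible membrane gene Ifitm1 rose by 3.01 ± 0.29 (adjusted p = 4.4e-07) and the secreted phospholipase gene Pla2g2d by 3.30 ± 0.62 (adjusted p = 0.0019; 4.43 ± 0.58, adjusted p = 2.9e-05 without the 18 h replicate 1). Akr1c18, a steroid-metabolising enzyme, fell by 4.69 (adjusted p = 9.6e-05) and Calca, which encodes the neuropeptide CGRP, was lower (-3.49 ± 0.70, adjusted p = 0.0047).

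The effects at 18 h and 3 d share the vehicle libraries. Across genes, which are not independent replicates, their log2 fold changes correlated at r = 0.67. Simulated unchanged groups that shared simulated vehicle libraries, all drawn from the vehicle means, gave 0.46 on average over 20 draws. The covariance was 0.463 against 0.042 simulated, a difference of 0.421. Among genes called in both comparisons, 1312 moved in the same direction and 19 in opposite directions (98.6% the same). The simulated groups gave at most 0 genes called the same way in both. No gene was changed in them, so that count follows from their setting and does not measure the overlap that shared controls give. Of the 1312 genes, 604 were higher in both, where independent lists of the same sizes would share 164. The other 708 were lower in both, where such lists would share 191. With the vehicle libraries divided between the comparisons in 20 ways, 335 to 694 genes (median 600) were called in the same direction, r was 0.54 to 0.62 and the covariance 0.394 to 0.479. Leaving out single libraries moved the number called in the same direction to 902 without vehicle replicate 4 and 1819 without vehicle replicate 3.

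In the authors' deposited table, 2913 genes at 18 h, 2249 at 3 d and 1086 between the times had an adjusted p below 0.05. A further column per comparison marked 1293, 990 and 662 genes as passing. That mark was not used, so a call by the authors here means only an adjusted p below 0.05. Against the authors' deposited table, 2615 of the 2734 genes called here at 18 h (95.6%), 2005 of 2064 at 3 d (97.1%) and 912 of 931 between the times (98.0%) were called by both, each in the same direction.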

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

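The tests of GC content and transcript length and of other splits of the libraries were chosen before their results were seen, and the other tests in this part after. Values of 82 genes, 30 lists and the total count were examined in each of the 3 groups for a library apart from the rest. Of these 339 tests, 17 flagged one. Chance alone gives about 1 in 20, so the number flagged is about what chance gives.

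Some vehicle libraries stood apart for single genes or lists. In vehicle replicate 3, Atp5g3 was 1850 CPM (2840 to 3290 in the other vehicle libraries), Id3 349 CPM (416 to 436), Ifitm1 24.4 CPM (39.6 to 48) and Il4ra 2.54 CPM (7.18 to 8.48). Ccl5 was 1480 CPM in vehicle replicate 5 (1080 to 1130), where the mean log2 CPM of cholesterol synthesis genes was 4.47 (4.25 to 4.31), and that of CD4+CD8+ thymocyte genes was 5.11 in vehicle replicate 4 (4.55 to 4.69).

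Among the 18 h libraries, replicate 1 had Klre1 at 20.1 CPM (2.57 to 4.42 in the others), Ly6c1 at 37.6 CPM (55.6 to 61.6), Nfkbia at 2410 CPM (995 to 1280) and Pla2g2d at 10.9 CPM (0.856 to 1.47). Its mean log2 CPM was 6.64 for NF-kB target genes (5.9 to 6.07) and 7.71 for oxidative phosphorylation genes (8.36 to 8.4). Trnp1 was 29.7 CPM in the 18 h replicate 4 (154 to 284). Among the 3 d libraries, Endou was 0.689 CPM in replicate 4 and 0 in the others, Oasl2 was 14.2 CPM in replicate 2 (31.9 to 33.1), and the NF-kB target mean in replicate 2 was 5.97 (6.16 to 6.19).

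By the direct test of 3 d against 18 h, 15 of 26 genes named in both comparisons with vehicle differed. No vehicle group was taken at 18 h, so time after injection alone could also give such differences. The 3 d minus 18 h log2 fold change was 4.54 for Ccl5, 2.23 for Tbx21 and 2.06 for Ifng. It was -3.11 for Trnp1, -2.97 for Mki67, -2.58 for Usp18, -1.77 for Il13, -1.60 for Il17rb and -1.49 for Zbtb16. It was -1.39 for Fkbp5, -1.37 for Rrm2, -1.36 for Cenpa, -1.23 for Hivep3, -1.16 for Ly6c1 and -0.74 for Pik3ip1. The Il17rb call was lost without the 3 d replicates 2 (adjusted p = 0.064), 3 (adjusted p = 0.083) or 4 (adjusted p = 0.053), with only the groups compared in the fit (adjusted p = 0.068) and with sample quality weights (adjusted p = 0.073).

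Between the same groups, 15 of 30 lists also differed. Median differences were 2.06 for NKT1 genes, 1.17 for NK cell and ILC1 genes, 1.15 for type 1 cytokine genes, 0.76 for macrophage genes, 0.51 for trafficking genes (mean 0.05), 0.37 for ribosome biogenesis genes and 0.29 for ribosomal protein genes. They were -2.17 for mitosis genes, -1.55 for interferon-stimulated genes, -1.53 for conventional T cell genes, -1.29 for ILC2 genes, -1.23 for NKT2 genes and also for CD4+CD8+ thymocyte genes, -0.86 for NKT precursor genes and -0.75 for glucocorticoid-induced genes. The called NK cell and ILC1 members, Klrb1c and Gzma, are also in the NKT1 list. With an estimated correlation only the NKT1, NKT2, interferon-stimulated (each adjusted p = 0.022) and NK cell and ILC1 (adjusted p = 0.027) lists kept the call, and the other 11 did not (adjusted p = 0.08 to 0.49). With a mean of at least 20 CPM required, CD4+CD8+ thymocyte genes lost it (-0.79, adjusted p = 0.15). The trafficking call was lost without the 18 h replicates 4 (adjusted p = 0.068) or 5 (adjusted p = 0.053) and with no filter on low counts (0.19, adjusted p = 0.091), and the macrophage call without the 18 h replicate 4 (adjusted p = 0.16) or the 3 d replicate 1 (adjusted p = 0.074).

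Vehicle replicate 3 lay between the vehicle and dexamethasone libraries, with a total of 1986973 counts and a quality weight of 0.47. RNA of the 18 h libraries mixed into it would move all genes by the same share of the way to those libraries. That share was 0.1 (0.06 to 0.15) for 146 genes over 4-fold higher and 0.43 (0.40 to 0.46) for 1259 genes under 2-fold. It was 0.05 for 13 glucocorticoid-induced genes. These values argue against mixing with 18 h RNA, while mixing with 3 d RNA was not tested. A trend on GC content and transcript length was argued against as the whole cause, since its deviation still correlated across genes with the 3 d effects at 0.6 after the trend was removed (0.61 before). A batch shared with the dexamethasone libraries stays open: setting it with the 3 d libraries against the other vehicle libraries called 2234 genes, above the 2064 of the real groups, and the labels give no batch. No biological explanation was tested for this pattern.

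NKT1 genes were lower at 18 h. Conventional T cells in the 18 h replicates 2 and 3 may account for part of this: without those libraries the median was -1.43 (-2.05 to -0.70), short of showing that the loss stays below -1. Cd8b1, which marks those libraries, does not tell conventional T cells from CD4+CD8+ thymocytes. Fewer NKT cells of every kind among those sorted would lower both subsets alike only if the cells in their place made neither set of transcripts. That was not tested. The NKT1 median minus the NKT2 median was -1.37 (-2.35 to -0.53), and the NKT17 median was -0.94, with 6 of 10 genes lower and 2 higher. The interval, which treats genes as independent, includes values above the -1 set for excluding this explanation. Fewer NKT cells of every kind therefore stay open for a part or the whole of the fall. An effect of dexamethasone at 18 h on NKT1 cells, which the groups name, remains open as well. Bulk counts do not tell fewer transcripts per NKT1 cell from fewer NKT1 cells among those sorted.

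Macrophage genes were higher at 3 d, and 16 of the 17 tested had a log2 fold change above 0 with a median of 1.16. Macrophages or their RNA among the sorted cells would give this, but the count restates the rise itself, so this explanation stays open. A larger number of the same macrophages as the whole cause of the Apoe rise stays open too. Apoe lay 3.6 of its SE above the median of the other macrophage genes (1.14), but it was picked after the values were seen as the largest rise of the list, so this decides nothing. The most abundant were Apoe at 3130 CPM, Lyz2 at 379 CPM, C1qb at 354 CPM and Ctss at 333 CPM at 3 d, and the cells had been sorted as NKT cells. An effect of dexamethasone on these transcripts within the sorted cells remains untested.

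For 18 h against vehicle, 1 of 100 splits of the libraries drawn from 126, the real one, called as many genes (2734, highest other 1231). Chance is therefore unlikely, though not excluded. For 3 d against vehicle, 2 of 100 did, the real one with 2064 and the split that sets vehicle replicate 3 with the 3 d libraries with 2234. Chance is unlikely there, though not excluded, and that library's place cannot be settled. For 3 d against 18 h, 1 of 100 did (931, highest other 594), so chance is again unlikely but not excluded.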

How the results depend on the processing

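Alternatives that left out chosen 18 h libraries or vehicle replicate 3, corrected GC content and length or used the axis covariate were chosen after the data were seen, and the others before. The counts of genes at 18 h, at 3 d and between the times (2734, 2064 and 931) stayed within 1.5 times under other scalings, filters and DESeq2 (2063 to 2922, 1658 to 2224 and 648 to 1054). Of 3755 gene values under 28 settings, 54 lost and 21 gained the call and 0 reversed, and of 2603 list values 105 lost and 33 gained it and 0 reversed. The median of all genes stayed under 0.05 in each scaling. Genes of a few CPM are limited by depth, and Areg and Rag1 were too low to test.

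A 2-fold minimum left 1206, 916 and 588 genes, and at 18 h raised the share higher from 49.5% to 60.9%. An adjusted p below 0.01 left 1630, 1037 and 454 genes and 599 called in the same direction at both times (1312 before). These follow from the stricter thresholds. With only the groups compared in the fit, 607 genes changed between the times, with fewer libraries. Sample quality weights gave 3129 genes at 3 d and 2042 shared between times, and the cause was not tested. The axis covariate left 539 and 228 genes and 99 shared, since it sets dexamethasone against vehicle replicate 3. Splitting the vehicle libraries gave a median of 600 shared, with fewer controls in each comparison. Calls shared with the authors' deposited table were 2615, 2005 and 912, and 1182, 898 and 579 with a 2-fold minimum.

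Leaving out 1 library gave 2160 (without vehicle replicate 4) to 3154 (without vehicle replicate 3) genes at 18 h, 1488 (without the 3 d replicate 3) to 2587 (without vehicle replicate 3) at 3 d, and 643 (without the 18 h replicate 3) to 1028 (without the 18 h replicate 4) between the times. Genes shared in direction ranged from 902 (without vehicle replicate 4) to 1819 (without vehicle replicate 3).

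The replicate numbers did not pair the samples. Deviations of same-numbered libraries correlated at -0.211 to 0.153 by the number in the title, with 1 of 13 pairs over 0.1, and at -0.211 to 0.034 by the number in the description, with 0 pairs over 0.1, and 2 and 0 libraries correlated best with their own number. With that number as a block, 2489, 1721 and 755 genes changed by the title and 2449, 1790 and 713 by the description. Between the times, Il17rb was not called with the title block (adjusted p = 0.057), and at 3 d Klre1 (adjusted p = 0.064) and C1qa (adjusted p = 0.06) were not called with the description block. Among lists at 3 d, gamma-delta T cell genes were not called with the title block (adjusted p = 0.051), nor NKT precursor genes with the description block (adjusted p = 0.055). Between the times, the title block brought in T cell receptor activation genes (adjusted p = 0.043), DNA replication genes (adjusted p = 0.042) and gamma-delta genes (adjusted p = 0.041), and the description block gamma-delta genes (adjusted p = 0.026).

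Fry did not call 10 lists that camera called: at 18 h ribosomal protein (adjusted p = 0.051) and conventional T cell genes (adjusted p = 0.098), at 3 d NKT1 (adjusted p = 0.19), type 1 cytokine (adjusted p = 0.078), interferon-stimulated (adjusted p = 0.057) and macrophage genes (adjusted p = 0.078), and between the times NKT precursor (adjusted p = 0.055), ribosome biogenesis (adjusted p = 0.057), conventional T cell (adjusted p = 0.069) and macrophage genes (adjusted p = 0.22). It called 5 that camera did not: at 18 h NKT17 (adjusted p = 0.0067), tissue repair (adjusted p = 0.0049), NK cell and ILC1 (adjusted p = 0.0049) and dendritic cell genes (adjusted p = 0.029), and at 3 d trafficking genes (adjusted p = 0.012).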

Other observations

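Several other gene groups were measured beside those already described. Of 11 tested tissue repair and growth factor genes, 2 were higher and 5 lower at 18 h (2 and 5 adjusted over the list alone), and 3 were lower at 3 d (3 adjusted over the list alone), and the list was not called at either time (-0.29, adjusted p = 0.44, and -0.31, adjusted p = 0.52). Of 6 ILC2 genes, which mark type 2 innate lymphoid cells, 4 were higher and 2 lower at 18 h (4 and 2 adjusted over the list alone; 0.91, adjusted p = 0.69). Of 8 regulatory T cell genes, 3 were higher and 1 lower at 3 d (3 and 1 adjusted over the list alone; 0.61, adjusted p = 0.52). Dendritic cell genes had 1 of 6 higher at each time against vehicle (1 and 1 adjusted over the list alone; adjusted p = 0.67 at 18 h and 0.87 at 3 d).

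Ribosome biogenesis genes, which were lower at 18 h, were higher at 3 d than at 18 h (0.37, adjusted p = 4.7e-05, adjusted p = 0.34 with an estimated correlation), with 5 of 29 higher (6 adjusted over the list alone), and at 3 d they were not called against vehicle (0.05, mean -0.01, adjusted p = 0.87). Ribosomal protein genes were also higher at 3 d than at 18 h (0.29, adjusted p = 2.9e-05, adjusted p = 0.27 with an estimated correlation), with 2 of 38 higher (1 adjusted over the list alone). Cholesterol synthesis genes were not called in any comparison (adjusted p = 0.96 at 18 h, 0.94 at 3 d and 0.89 between the times).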
